A study of Drosophila melanogaster with 16 samples.

How the data were processed

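RNA levels were measured on 16 one-colour Agilent arrays of Drosophila S2 cells. Cells had been exposed for 5 days to dsRNA against GFP (control), REPTOR (CG13624) or REPTOR-BP (CG18619), and then for 2 h to 20 nM rapamycin or to its solvent, ethanol at 1:1000. The design gave 3 arrays per group for control and REPTOR knockdown and 2 per group for REPTOR-BP knockdown, described by the submitters as biological replicates. Each replicate is 1 array, and the p-values measure the spread between these arrays.

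Each array file, per the file headers, was written by Agilent Feature Extraction 10.7, and its values are intensity per spot, background-subtracted and spatially detrended within the array, with no scaling between arrays. The same deposited files hold the median intensity of each spot and of its local background, and other columns with flags for spots well above background, saturated spots and outlier spots. The deposited series table holds intensity per probe on a linear scale, with nearly the same distribution in every column, as after quantile normalization. The method behind that table is not stated, and it served only as an alternative. The files hold no mean spot signal, so the alternative with normexp background correction (offset 50) used the median signals in its place.

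The processed intensity was put on the log2 scale and the 75th percentile of each array was subtracted. Outlier spots were left out, 76 to 232 of 43602 per array, and the remaining spots of a probe were averaged. The 32162 probes address 25760 targets, where a target is the transcript, clone or cluster ID that the array design gives, and each target was represented by its brightest probe. Targets were tested when their probe was well above background on every array of at least 1 group, which left 15314. Between 56.9% and 63.3% of probes were well above background per array, 0 spots were saturated, and the 75th percentile of intensity ran from 1837 to 4242. Arrays give no counting error, so the number of arrays limits the precision. A fold change is given as a bound where a target was well above background on every array of one group and on none of the other. Each dim array was set to its measured level or to the dimmest level flagged on it as well above background, whichever was higher. Where the measured levels were higher, the bound equals the measured change. It makes no allowance for the spread between arrays.

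Gene names were taken from a RefSeq gene table of the Release 6 assembly by exact match of the IDs. Of the probes, 20979 carry only a FlyBase transcript ID, and 12 of these could be named. Another 428 carry a RefSeq ID, of which 219 could be named. In all, 384 probes received the names of 324 genes, and 208 named targets were among those tested. No probe could be named as REPTOR or REPTOR-BP, so the planned check of the knockdown itself was not run, and most targets are reported as counts.

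The model was a limma fit (limma 3.58.1 under R 4.3.3) of the 6 group means to all 16 arrays, with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all targets tested. A target was called at an adjusted p below 0.05. The standard errors given with log2 changes come from this fit. The 8 comparisons were rapamycin against ethanol in each of the 3 kinds of cells, each knockdown against control in ethanol, and the differences between the 3 rapamycin responses. The share of a response that a knockdown kept was measured on targets selected without 1 pair of control arrays and then compared with that held-out pair, over 3 hold-outs. Lists of genes were tested with limma's camera (preset correlation 0.01), for lists with at least 3 measured members. The tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

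The groups, comparisons, tests, alternative settings, rule for named genes and 32 gene lists were chosen before the data were examined. The rule took genes that had a name, were well above background on all arrays compared, passed the test and had every array of one group above every array of the other. From these it took the largest changes in each direction, up to 12 for rapamycin in control cells, 8 for each knockdown in ethanol, 6 for rapamycin in each knockdown, 10 for each difference against control and 5 for the difference between the knockdowns. It added the 4 largest bounds per comparison and up to 4 members of each list, whether or not they passed. Named genes that passed the test but not the rest of the rule are described as outside it, and were chosen after their values were seen.

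The arrays lay on 5 slides read on 3 days. Whether replicate numbers pair the arrays was checked on the deviations of each array from its group. Arrays of equal number correlated in control cells (0.80, 0.66 and 0.73 for replicates 1, 2 and 3), and in REPTOR knockdown for replicates 1 and 3 (0.57 each) but not 2 (-0.30), whose arrays lay on different slides. In REPTOR-BP knockdown, whose arrays all shared a slide, arrays of equal number correlated at 0.69. Across groups of control and REPTOR knockdown cells, arrays on the same slide had a median correlation of 0.66 (15 pairs) and arrays on other slides of -0.29 (39 pairs). The model, chosen before the data were examined, used no pairing and no slide block. Differences between slides therefore enter its spread, and slide and replicate blocks were alternatives.

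The alternatives were normexp background correction, quantile normalization, median scaling, the deposited table, no filter on dim probes, only probes well above background on all arrays, the mean of a target's probes, a replicate block, slide as a fixed or a random block, an intensity trend with robust moderation, only the arrays of the groups compared, a minimum of 1.5-fold, and leaving out each array in turn. Scan day as a fixed block was added after seeing the data. The procedure was tested on simulated data with 15270 targets, of which 67, 67 and 66 per comparison were changed 1.5-, 2- and 4-fold. For rapamycin in control cells it recovered 32.8%, 64.2% and 89.4% of these. For rapamycin in REPTOR-BP knockdown these were 19.4%, 47.8% and 80.3%, and for the difference between REPTOR knockdown and control 11.9%, 40.3% and 81.8%. Between 3 and 10 unchanged targets were called per comparison. The simulated arrays were drawn independently, without the slide differences that real arrays share. Recovery and false calls can therefore differ in the real data. Kept shares made as 50% and 80% were measured as 48.4% and 80.0%. That check used control changes of 1.5 on the log2 scale in either direction. The real selected targets had smaller medians on held-out control arrays, 0.609 to 0.692 for increases and -0.547 to -0.745 for decreases. Kept shares at changes of that size were not tested.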

Results

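S2 cells, an embryo-derived Drosophila line with macrophage-like properties, were profiled after 2 h of rapamycin, an inhibitor of the TORC1 kinase, with or without knockdown of REPTOR or REPTOR-BP, both basic leucine zipper proteins. The 6 groups held 3 arrays each for control (GFP dsRNA) and REPTOR knockdown and 2 each for REPTOR-BP knockdown. The comparisons ask how cells respond to rapamycin, and how far that response depends on each of the 2 factors. Arrays of one group correlated at 0.986 to 0.992 across targets. All 4 REPTOR-BP arrays shared a slide that held no other kind of cells, while control and REPTOR arrays lay together on 3 slides and 1 REPTOR array alone on another. Gene names were available for 208 of the 15314 targets tested.

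In control cells, rapamycin raised single genes that act upstream of TORC1, in lipid metabolism and in autophagy, none of them members of the gene lists. The GATOR2 subunits mio and Wdr59, parts of a complex that acts upstream of TORC1, rose 1.94-fold (log2 change 0.95 ± 0.12, SE, n = 3 arrays per group, adjusted p = 0.0006) and 1.53-fold (0.61 ± 0.08, adjusted p = 0.00049). Ypel, of the conserved Yippee-like family, rose 2.15-fold (1.10 ± 0.09, adjusted p = 6.5e-05). The alkaline ceramidase bwa rose 1.94-fold (0.95 ± 0.15, adjusted p = 0.0018) and mino, a glycerol-3-phosphate acyltransferase, rose 1.80-fold (0.85 ± 0.11, adjusted p = 0.0006). The BEACH-domain protein bchs, which acts in autophagy, rose 1.53-fold (0.62 ± 0.08, adjusted p = 0.0006). CG33293 rose 2.48-fold (1.31 ± 0.28, adjusted p = 0.013), although its adjusted p was 0.38 with normexp background correction. Smaller increases, from 0.22 to 0.51 on the log2 scale, were found for lncRNA:CR42862, CG16865, CG2685, the translation initiation factor subunit eIF3l and the kinase Dyrk3. Each of these 12 genes was higher in 3 of 3 pairs of arrays, which the rule for named genes requires.

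The non-coding RNA lncRNA:CR42746 was well above background on no control array in ethanol and on every array in rapamycin. Its bound, 4.44-fold higher, equals its measured log2 change of 2.15 ± 0.34 (adjusted p = 0.0021). Pde1c, a phosphodiesterase, had a bound of 1.68-fold higher but did not pass the test (adjusted p = 0.2). NimC3, a receptor of the Nimrod family, passed the test outside the rule for named genes, with a log2 change of 1.46 ± 0.38 (adjusted p = 0.032), an inexact size since NimC3 was well above background on 1 of 3 ethanol arrays. Among targets without a gene name, the transcript FBtr0076127 rose 3.83-fold (1.94 ± 0.16, adjusted p = 6e-05) and FBtr0302979 fell 3.29-fold (-1.72 ± 0.22, adjusted p = 0.00061).

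The genes that fell in control cells included hosts of small nucleolar RNAs, mitochondrial ribosomal proteins and the aldolase Ald1. Uhg5, a snoRNA host gene, fell 2.10-fold (log2 change -1.07 ± 0.10, SE, n = 3, adjusted p = 0.00011) and its counterpart Uhg2 fell 1.54-fold (-0.63 ± 0.16, adjusted p = 0.030). Ald1 fell 1.77-fold (-0.82 ± 0.12, adjusted p = 0.0016), and the cyclophilin Cyp1 had a log2 change of -0.64 ± 0.16 (adjusted p = 0.026). The TORC1 inhibitor chrb, the fly homologue of REDD1, fell 1.78-fold (-0.83 ± 0.20, adjusted p = 0.024). The RNA of the signal recognition particle, 7SLRNA:CR32864, fell 2.15-fold (-1.11 ± 0.29, adjusted p = 0.033). CG12224 (-0.70), Pa1 (-0.52) and the RNA polymerase subunit Polr2F (-0.46) also fell, and so did ND-B17.2, a subunit of respiratory complex I, outside the rule (-0.35, adjusted p = 0.030). The 12 genes named by the rule, with mRpL52, mRpS16 and mRpL14 among them, were lower in 3 of 3 pairs, as the rule requires.

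Of the 32 gene lists, 11 had a measured member with a name and 3 had enough for camera, so most pathways could not be described. All 3 measured mitochondrial ribosomal proteins fell in control cells, namely mRpL52 1.53-fold (-0.61 ± 0.12, adjusted p = 0.0084), mRpS16 1.47-fold (-0.56 ± 0.07, adjusted p = 0.0006) and mRpL14 1.39-fold (-0.48 ± 0.11, adjusted p = 0.019). Their median log2 change was -0.557, the camera test gave an adjusted p of 0.00018, and 3 of 3 passed when adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.072 with an estimated correlation). Of the cytosolic ribosomal proteins, 0 of 3 passed limma's test, either over all targets or adjusted over the list alone. Their log2 changes were 0.14 for RpL23, 0.13 for RpS18 and 0.35 for RpS29 (camera adjusted p = 0.68), and those of RpS18, RpL23 and RpS29 turned negative without control rapamycin replicate 1 (-0.04, -0.04 and -0.52). Of the respiratory chain list, 0 of 3 passed limma's test over all targets, with -0.29 for cype, -0.25 for RFeSP and -0.25 for UQCR-C2 (camera adjusted p = 0.14). The lists for TORC1 and insulin signalling, FOXO targets and the amino-acid stress response had chrb as their single measured member, which fell. Single members of other lists did not pass: the vacuolar ATPase subunit Vha13 at -0.33 (adjusted p = 0.32), the RNA polymerase I subunit Polr1B, well above background on 0 of 3 rapamycin arrays (0.088), the proteasome ATPase Rpt1 at -0.12 (0.45) and the transcription factor CrebA at -0.16 (0.82). In a fit with slide as a fixed block, Vha13 (adjusted p = 0.0051), Polr1B (0.033), eIF1 (0.010), cype (0.049) and RFeSP (0.0012) passed. Of the translation factors, eIF3l rose and eIF1 had -0.30 (adjusted p = 0.34). Markers of hemocytes, neurons, muscle, fat body and germline had no measured member with a name.

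Across all targets, 1381 passed the test in control cells, 705 higher and 676 lower, with median log2 changes of 0.52 and -0.53. Of these, 71 of the higher and 50 of the lower changed at least 2-fold. A fit with slide as a fixed block called 4233, and all 1381 targets were again past the threshold. Ypel, bwa, mio, mino, bchs, Wdr59, Uhg5, Ald1, mRpS16 and mRpL52 kept their call under every alternative run for single genes, leaving out each array included, and each of the other genes called here lost it under at least 1. The count was 828 without control EtOH replicate 2, 551 with median scaling (224 higher) and 94 when only these 6 arrays were fitted.

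**Figure D1:**
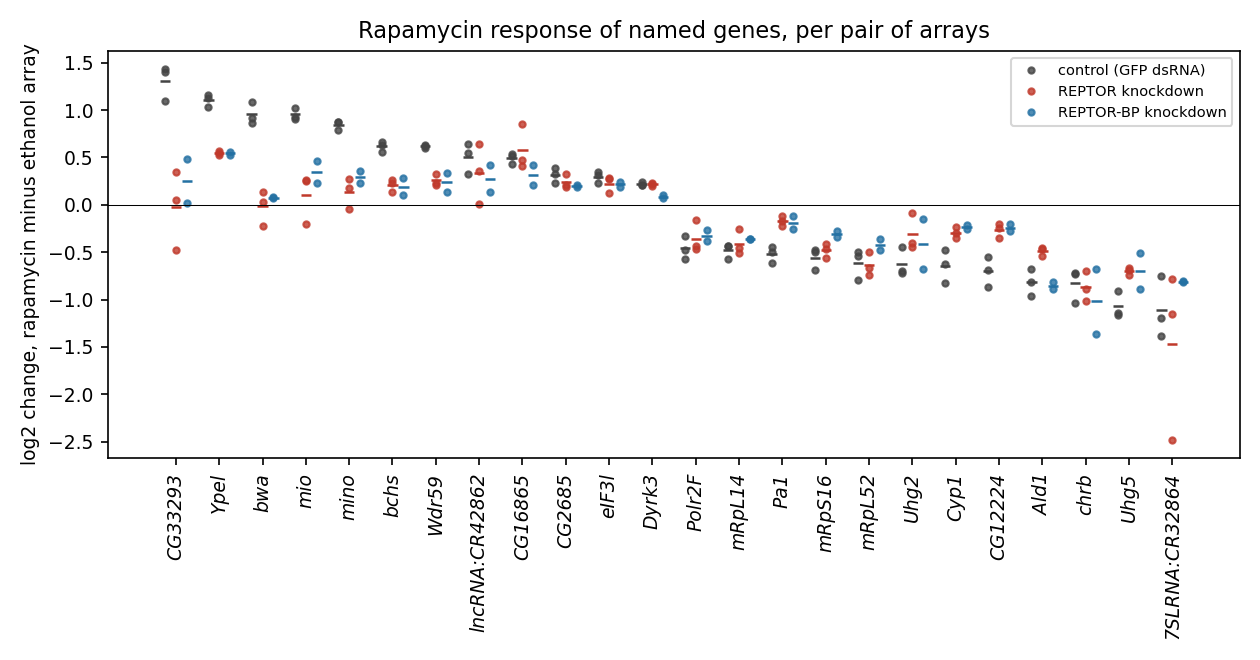
Rapamycin response of 24 named genes, as the log2 change from the ethanol to the rapamycin array for each pair of arrays, in control cells (grey), REPTOR knockdown (red) and REPTOR-BP knockdown (blue); short lines are group means. The knockdown values of bwa, mio and mino lie between -0.22 and 0.46 while their control values lie between 0.79 and 1.08, and chrb and the mitochondrial ribosomal genes are negative in each kind of cell.

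In REPTOR knockdown cells, rapamycin still lowered Uhg5, chrb and mitochondrial ribosomal genes, and the single named gene called as higher over all arrays was Ypel. Ypel rose 1.46-fold (log2 change 0.55 ± 0.09, SE, n = 3 arrays per group, adjusted p = 0.0089, higher in 3 of 3 pairs, as the rule requires). Uhg5 fell 1.63-fold (-0.70 ± 0.10, adjusted p = 0.0048), chrb 1.83-fold (-0.87 ± 0.20, adjusted p = 0.045) and 7SLRNA:CR32864 2.77-fold (-1.47 ± 0.29, adjusted p = 0.019). The size for 7SLRNA:CR32864 leaned on replicate 2, with -0.78, -2.48 and -1.15 in the 3 pairs and -0.99 with slide as a fixed block. The guide RNA snoRNA:Psi28S-291 fell 1.76-fold (-0.81 ± 0.18, adjusted p = 0.037). The named genes that fell under the rule were lower in 3 of 3 pairs, which the rule itself requires. The arrays of replicate 2 lay on different slides. Of the 24 genes named for control cells, 6 passed here over all arrays and 15 with slide as a fixed block, 8 of them lower, such as Ald1 (-0.49, adjusted p = 0.0041 with the block). The 7 higher ones with the block were Ypel (0.57), CG16865 (0.45, adjusted p = 0.0028), eIF3l (0.28, 0.016), lncRNA:CR42862 (0.49, 0.017), Wdr59 (0.24, 0.043), Dyrk3 (0.20, 0.043) and mino (0.24, 0.044). Polr1B, outside the rule, was also lower (adjusted p = 0.037), but was well above background on 1 of 3 ethanol and 0 of 3 rapamycin arrays, so no size is given. Of the mitochondrial ribosomal proteins, mRpL52 (-0.64 ± 0.12, adjusted p = 0.018) and mRpS16 (-0.48 ± 0.07, adjusted p = 0.0054) fell, and mRpL14 had -0.41 (adjusted p = 0.082, or 0.0066 with slide as a fixed block). All 3 passed when adjusted over the list alone, and camera gave an adjusted p of 6.5e-05, or an adjusted p = 0.072 with an estimated correlation. The cytosolic ribosomal and respiratory chain lists had camera adjusted p-values of 0.96 and 0.17.

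In all, 393 targets passed in REPTOR knockdown cells, 134 higher and 259 lower, with median log2 changes of 0.475 and -0.578. Of the increased targets, 112 were shared with control cells where chance would give 6.17, and of the decreased targets 242 where chance would give 11.4. These chance values assume independent calls. Both comparisons take a target's spread from the same fit, which favours shared calls, so the values are low as a baseline. Under the slide block 1480 passed, 757 of them higher, and with median scaling 51 passed, 8 of them higher. The calls of Ypel, Uhg5 and mRpS16 were lost with median scaling alone. Those of chrb, snoRNA:Psi28S-291, mRpL52, 7SLRNA:CR32864 and Polr1B were lost under 9, 5, 4, 3 and 10 alternatives. Leaving out any of the 6 arrays gave 139 to 253, lowest without REPTORkd rapamycin replicate 3, and fitting these arrays alone gave 0, with 2232 at an unadjusted p under 0.05 in the limma fit of all arrays.

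In REPTOR-BP knockdown cells, no named gene passed the test for rapamycin over all arrays, while 11 of the 24 genes named for control cells passed with slide as a fixed block. The values of those called in control cells were 0.54 for Ypel (adjusted p = 0.079, higher in 2 of 2 pairs), -0.70 for Uhg5 (0.056) and -0.85 for Ald1 (0.056), each lower in 2 of 2 pairs. For chrb the log2 change was -1.02 (adjusted p = 0.12). With the slide block the adjusted p was 0.015 for Ypel, 0.0088 for Uhg5, 0.0029 for Ald1, 0.018 for chrb, 0.028 for mRpL52, 0.040 for mRpS16, 0.034 for mRpL14, 0.036 for 7SLRNA:CR32864, 0.026 for Polr2F and, among increases, 0.024 for CG16865 (0.32) and 0.037 for mino (0.30). Polr1B had a bound of 2.78-fold lower (adjusted p = 0.1) and the transcription factor grh one of 1.87-fold higher (adjusted p = 0.99), and neither passed. The mitochondrial ribosomal proteins had a median of -0.361, with 0 of 3 past the threshold over all targets and 3 of 3 adjusted over the list alone. Camera gave an adjusted p of 0.00018 for them, or an adjusted p = 0.072 with an estimated correlation, and 0.96 and 0.17 for the cytosolic ribosomal and respiratory chain lists.

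With 2 arrays per group, 29 targets passed, 7 higher and 22 lower, with median log2 changes of 0.675 and -0.819. Of the 22 lower targets, 21 were also lower in control cells (0.971 by chance), and 21 were also lower in REPTOR knockdown (0.372 by chance). These chance values, too, assume independent calls, although the comparisons share the spread of each target. FBtr0302979, lower in control cells and in REPTOR knockdown (-1.23, adjusted p = 0.013), was again lower, with -1.77 (adjusted p = 0.03). A slide block raised the count to 911, all 29 again among them. It was 0 to 8 when any of the 4 arrays was left out, 0 without BPkd rapamycin replicate 1, and 4 with median scaling.

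**Figure D2:**
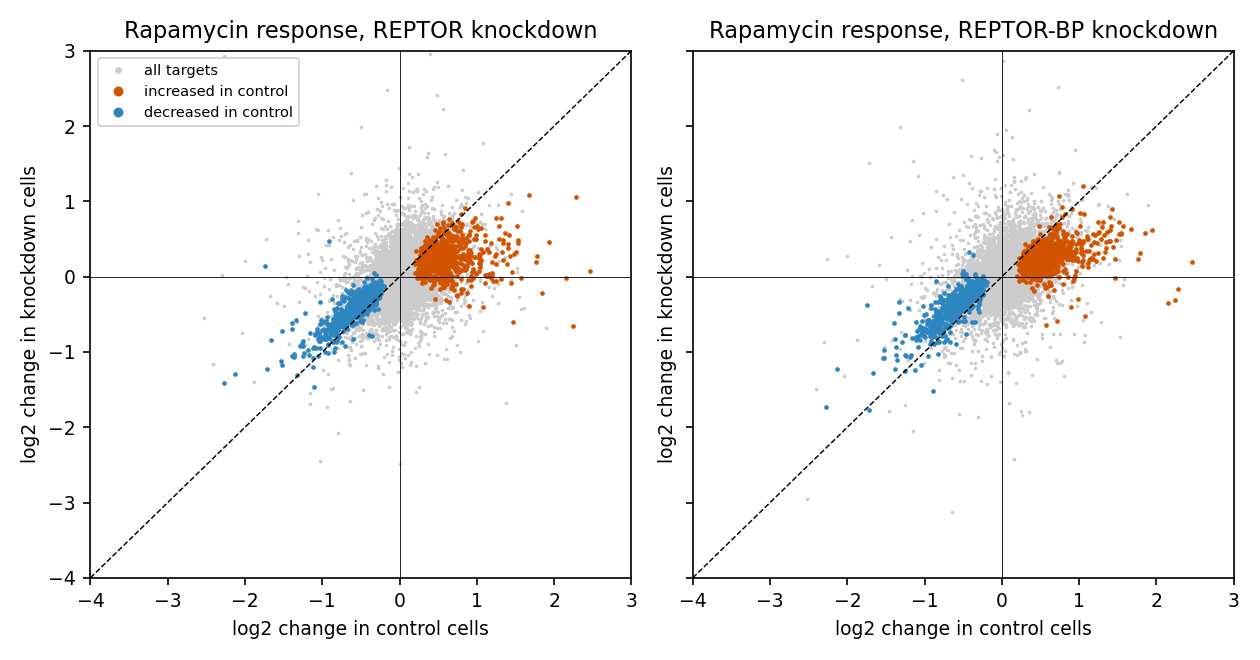
Log2 change after rapamycin in control cells (horizontal) against REPTOR knockdown (left) and REPTOR-BP knockdown (right, vertical), each point a target, with the 705 targets increased in control cells in orange and the 676 decreased in blue. The decreased targets follow the dashed line of equal change more closely than the increased ones, many of which lie between that line and 0.

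The increase after rapamycin was smaller in REPTOR knockdown than in control cells for named genes such as mio, mino and CG33293, though none passed the test of the difference over all arrays. The difference in log2 change was -0.85 ± 0.17 for mio (SE, adjusted p = 0.11), -0.71 ± 0.15 for mino (adjusted p = 0.15) and -1.34 ± 0.40 for CG33293 (adjusted p = 0.57). With slide as a fixed block these 3 passed, with -0.69 for mio (adjusted p = 0.040), -0.61 for mino (0.022) and -1.07 for CG33293 (0.031). Within the slides that held both kinds of cells, the differences for replicates 1 and 3 were -0.67 and -0.77 for mio, -0.60 and -0.61 for mino, and -1.04 and -1.06 for CG33293. These 3 genes were picked for passing with the block, and the within-slide values come from arrays that also served to pick them. The gene bwa, at -0.01 in REPTOR knockdown against 0.95 in control cells, did not pass with the block. The RNA lncRNA:CR42746 also passed with the slide block, but it was well above background on 3 of 3 control arrays in rapamycin and on 0 of 10 knockdown arrays, so the size of its difference is not given. For Ypel the difference was -0.55 ± 0.13 (adjusted p = 0.21), and for chrb it was -0.04 ± 0.28 (adjusted p = 1). For the mitochondrial ribosomal list camera gave an adjusted p of 0.68.

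The test of the difference called 22 targets, none with a gene name, all 22 with a smaller response in REPTOR knockdown and all 22 increased in control cells. Their median difference was -1.06, and the median of these targets kept 12.9% of its increase. Both values come from the arrays and the test that selected these targets, which favours a large difference and a small share. FBtr0076127 was among them (difference -1.47, adjusted p = 0.031). Within slides the 22 targets had median differences of -0.99 and -1.03 for replicates 1 and 3, on arrays that also served to select them. In a fit with slide as a fixed block 111 targets were called, 108 of them negative, of which 93 were increased in control cells. Leaving out any of the 12 arrays lowered the count, to between 1 (control rapamycin replicate 3 among others) and 10 (REPTORkd EtOH replicate 1), and median scaling gave 0, with 521 at an unadjusted p under 0.05 in the limma fit as reported.

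In REPTOR-BP knockdown, the named genes had differences from control cells of like size, and again none passed over all arrays. They were -0.61 for mio (adjusted p = 0.086 with slide as a fixed block), -0.55 for mino (0.051) and -1.06 for CG33293 (0.053). With the block lncRNA:CR42746 passed here too (adjusted p = 0.00063), with no size given for the same reason of background. The test over all arrays called 1 target, FBtr0072396, named after its value was seen, which rose in control cells (1.07, adjusted p = 0.00034) and had a difference of -1.60 (adjusted p = 0.047) in REPTOR-BP knockdown and of -1.47 (adjusted p = 0.017) in REPTOR knockdown. The slide block called 16 targets, 14 of them negative, and 13 were shared with REPTOR knockdown. All 22 targets called in REPTOR knockdown were negative here too, but both differences use the same control arrays, which favours equal signs. The count was 0 with median scaling, quantile normalization and the deposited table, and when any array but control EtOH replicate 2 (1) or BPkd EtOH replicate 1 (2) was left out, against 495 at an unadjusted p under 0.05 in the limma fit as reported.

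Between the 2 knockdowns, limma called 0 targets for a difference in the rapamycin response, with 175 at an unadjusted p under 0.05. The log2 difference, REPTOR-BP minus REPTOR knockdown, was -0.01 ± 0.15 for Ypel, 0.00 ± 0.16 for Uhg5 and -0.36 ± 0.20 for Ald1 (adjusted p = 1 each). In the self-test, with arrays drawn independently, this comparison recovered 34.3% of targets that differed 2-fold, so differences of that size could be missed.

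On targets selected and measured on separate control arrays, REPTOR knockdown kept 37% ± 2.5 (SD, n = 3 hold-outs) of the increase and 76.9% ± 9.7 of the decrease after rapamycin. REPTOR-BP knockdown kept 42.2% ± 1.6 of the increase and 68.9% ± 7.3 of the decrease. Each hold-out rested on 248 to 353 increased and 275 to 362 decreased targets. The knockdown arrays were the same in every hold-out, so these SDs do not hold the spread between knockdown arrays. Named genes went both ways. Of the 12 increased genes, 7 kept at most 50% of their control change in REPTOR knockdown, such as bwa (-0.01 against 0.95), mio (0.10 against 0.95) and bchs (0.21 against 0.62), and 5 kept more, such as CG16865 (0.57 against 0.50), Dyrk3 (0.22 against 0.22) and eIF3l (0.22 against 0.30). The 7 had the larger control increases (0.61 to 1.31) and the 5 the smaller ones (0.22 to 0.51). In control cells the calls of the 5 were lost under 4 to 12 alternatives. Of the 7, CG33293 alone lost its call, under 3. Replicate 2, with its REPTOR arrays on different slides, lowered the values of mio (0.26, -0.20 and 0.25 per pair) and bwa (0.14, -0.22 and 0.03). It raised that of CG16865 (0.41, 0.85 and 0.47). Of the 12 decreased genes, 8 kept more than 50%, such as chrb (-0.87 against -0.83) and mRpL52 (-0.64 against -0.61), and 4 kept at most that, namely Cyp1 (-0.29 against -0.64), Pa1 (-0.17 against -0.52), CG12224 (-0.26 against -0.70) and Uhg2 (-0.31 against -0.63). Their median kept shares were 46.3% and 71.8% in REPTOR knockdown and 40.1% and 67.8% in REPTOR-BP knockdown, measured on the arrays that selected the genes. Per pair of arrays, the 705 increased targets had medians of 0.495, 0.546 and 0.526 in control cells, 0.236, 0.216 and 0.240 in REPTOR knockdown, and 0.273 and 0.195 in REPTOR-BP knockdown. The 676 decreased targets had -0.459, -0.548 and -0.566, then -0.351, -0.402 and -0.403, then -0.341 and -0.324. The medians in control cells come from the arrays that selected the targets and are therefore somewhat inflated.

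**Figure D3:**
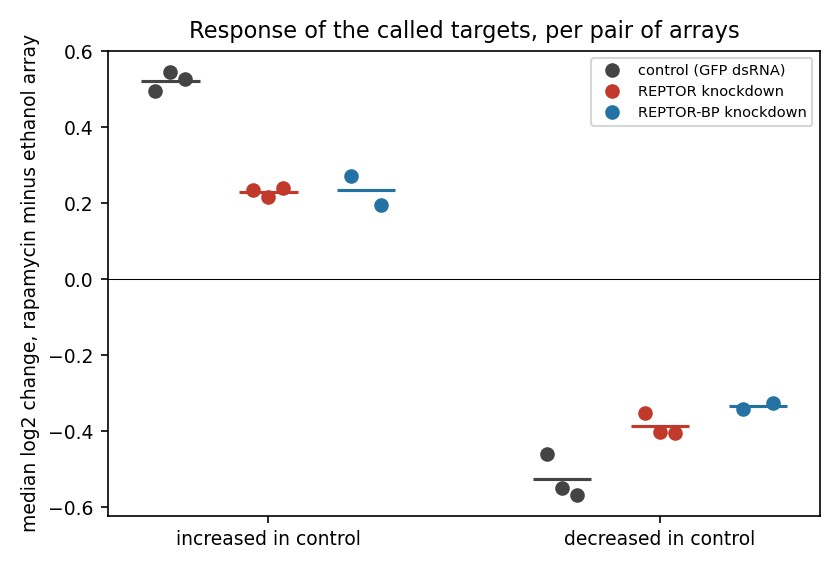
Median log2 change from the ethanol to the rapamycin array over the 705 targets increased (left) and the 676 decreased (right) in control cells, each point a pair of arrays and each line the mean of its group. The increased targets sit at 0.495 to 0.546 in control cells and at 0.195 to 0.273 in the knockdowns, and the decreased ones at -0.566 to -0.459 and -0.403 to -0.324.

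Across the 15314 targets, which are not independent replicates, the response in control cells correlated with that in REPTOR knockdown (Pearson r = 0.49, Spearman rho = 0.531) and in REPTOR-BP knockdown (0.535 and 0.601). The 2 knockdown responses correlated at 0.399 and 0.455. The 2 differences from control cells correlated at 0.46 and 0.439, but they share the control arrays, and simulated groups without any difference gave a mean r of 0.448 and at most 0.481. With separate control pairs for the 2 differences, r was 0.0555 to 0.219.

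Without rapamycin, REPTOR knockdown changed few targets and no gene with a name. The transcript FBtr0075839 fell by 2.10 on the log2 scale (± 0.14, SE, n = 3 arrays per group, adjusted p = 9.3e-05). Named genes called after rapamycin had values of -0.26 ± 0.09 for Ypel, 0.15 ± 0.20 for chrb and -0.02 ± 0.07 for mRpS16, and -0.35 ± 0.19 was found for the ARID-domain transcription factor retn (adjusted p = 1 each). The 3 lists had camera adjusted p-values of 0.88 for the mitochondrial ribosomal proteins, 0.92 for the cytosolic ones and 0.92 for the respiratory chain.

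In all, 17 targets passed in REPTOR knockdown without rapamycin, 9 higher with a median log2 change of 0.78 and 8 lower with -1.70. Within the slides of replicates 1 and 3 the higher targets had medians of 0.67 and 0.75 and the lower ones -1.99 and -1.65, on arrays that also served to select them. The slide block gave 38 calls, and 13 of the 17 were among them. Leaving out an array gave 9 to 12, lowest without control EtOH replicate 2, and fitting the 6 arrays alone gave 0, with 521 at an unadjusted p under 0.05 in the limma fit of all arrays.

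REPTOR-BP knockdown without rapamycin went with lower levels of retn and of several poorly characterised genes. The transcription factor retn was 2.89-fold lower (log2 change -1.53 ± 0.21, SE, n = 2 against 3 arrays, adjusted p = 0.0024), with every knockdown array below every control array, as the rule requires. The non-coding RNAs lncRNA:alphagamma-element:CR32865 (-0.73 ± 0.17, adjusted p = 0.036) and lncRNA:CR42767 (-0.63 ± 0.14, adjusted p = 0.028) were also lower. The zinc transporter ZnT63C (0.52 ± 0.12, adjusted p = 0.035) and lncRNA:CR31044 (0.44 ± 0.11, adjusted p = 0.042) were higher. Outside the rule, CG13545 (-1.5, adjusted p = 0.004) and CG14330 (-1.22, 0.040) were lower, and CG14191 (1.63, 0.048) and CG9133 (0.73, 0.032) were higher. These 4 sizes are inexact, since CG13545 and CG14330 were well above background on 1 of 2 knockdown arrays and CG14191 and CG9133 on 2 of 3 control arrays. The UDP-glycosyltransferase Ugt303A1 passed as lower (adjusted p = 0.018), but it was well above background on 0 of 2 knockdown and 1 of 3 control arrays, so no size is given. CG18233 was well above background on neither knockdown array and had a bound of 2.45-fold lower (adjusted p = 0.0046). The other named bounds were 2.28-fold lower for CG32260 (adjusted p = 0.095), 1.76-fold for SP2353 (0.3) and 1.18-fold for puf (0.5), and none of them passed. The log2 changes of CG13545 (0.03), CG18233 and Ugt303A1 turned positive with normexp background correction. The mitochondrial ribosomal, cytosolic ribosomal and respiratory chain lists each had a camera adjusted p of 0.68. Adjusted over the list alone, 0, 1 and 1 of their 3 measured members passed limma's test.

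In all, 708 targets passed in REPTOR-BP knockdown without rapamycin, 157 higher and 551 lower, with median log2 changes of 0.651 and -1.08. The knockdown arrays shared a slide with no control array, so no slide gives a value of its own and a fit with slide as a fixed block has no estimate. With slide as a random block 112 targets passed, retn (adjusted p = 0.024) and CG13545 (adjusted p = 0.030) being the named ones. The call of retn was kept under every alternative run for single genes, leaving out each array included. Each other named call was lost, with its direction kept, under 1 or more of these alternatives. These were 12 for lncRNA:CR42767, 11 each for lncRNA:CR31044, lncRNA:alphagamma-element:CR32865 and CG14191, and 10 each for ZnT63C and CG14330. They were 9 for CG9133, 8 for Ugt303A1, 3 for CG18233 and 1 for CG13545. The excess of lower targets turned with median scaling (430 of 826 higher). The count was 134 with normexp background correction, 192 without BPkd EtOH replicate 1, 299 without BPkd EtOH replicate 2, 379 without control EtOH replicate 1, 421 without control EtOH replicate 2 and 3 when these 5 arrays were fitted alone.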

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

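The tests of scan day, of slide and of a shift in the array scale were chosen after the result was seen, as were scan day as a block and the regrouping with slide as a block; the other tests were set out beforehand.

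The rapamycin response differed between groups, by the test of the difference itself, for 22 targets that responded less in REPTOR knockdown than in control cells and for 1 target, FBtr0072396, that responded less in REPTOR-BP knockdown. The 6 control and 6 REPTOR arrays were also regrouped: 14 of 100 groupings, the real one included, called as many as 22, the highest other 2231, so chance is not excluded by this count. Of the 13 others that called as many, 8 called over 100 targets, several times the real count, which points to the slides. With slide as a fixed block 10 of these 13 called at most 9. Over all 100 groupings with that block, the real one called 111 and 3 others more, the highest 430.

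For the 2-group counts the 10 possible splits are too few for a share under 0.05. The real split alone reached its count, 1 of 10 each time, with 1381 targets against at most 0 in the others for rapamycin in control cells, 393 against 0 in REPTOR knockdown and 17 against 0 for REPTOR knockdown without rapamycin. In control cells, where the numbers pair the arrays, 4 splits part every pair, and those other than the real one also called 0.

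REPTOR-BP knockdown without rapamycin gave 708 calls, on a slide of its own read on the last day. Slide cannot be told apart from the knockdown, since these arrays shared it with no other cells: 112 targets passed with slide as a random block, retn among them, but that block widens the error of this comparison whichever is the cause. Nor can scan day. A REPTOR array in ethanol read on that day departed from its 2 partners along the same targets with a slope of 0.0722. The SE of 0.013 is over targets, which are not independent replicates. The slopes of the partners, -0.0588 and -0.0134, offset it by construction, since each array was set against the other 2. It is a single array, so its slope cannot decide. With scan day as a block 174 targets passed. An effect of the lower REPTOR-BP level itself stays open and could not be separated from the slide.

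Rapamycin gave 29 calls in REPTOR-BP knockdown against 1381 in control cells. The smaller number of arrays is argued against as the whole cause, since fits with 2 control arrays per group called 523 to 851. Compression of the signal on the dimmer slide alone would shrink increases and decreases alike, but the kept share of the decrease exceeded that of the increase by 26.7 percentage points, more than the sum of their SDs. A shift of the array scale added to compression would have to be -0.0861, or -0.24 with median scaling. The median move of targets not called in control cells lay above the shift needed in 3 of 3 hold-outs under each of 5 scalings. Scaling aligns this bulk of targets and holds its move near 0, so the test cannot decide on compression with a shift. A weaker response in these cells may remain as a hypothesis, although 911 targets passed with slide as a fixed block and the kept shares of 42.2% and 68.9% show that much of the response was still there.

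In REPTOR knockdown, increases after rapamycin were kept less than decreases. A shift of the array scale alone would move both sets alike, but against held-out control pairs the increased targets were lower (mean difference of medians -0.413) and the decreased ones higher (0.158 ± 0.085, SD) in 3 of 3 hold-outs. With an equal loss of both responses a shift of -0.129 would be needed, or -0.256 with median scaling. Targets not called in control cells moved by -0.00964 to 0.00541. These are the bulk of targets, which scaling aligns, so their move lies near 0 largely by construction. It cannot decide on such a shift, which stays open. Dim probes are argued against by a kept share of 31.0% ± 3.1 (SD, n = 3 hold-outs) in the brighter part of the increased targets, and selection on control values high by chance by shares that differed by 39.9 percentage points on held-out control arrays. A lesser induction of these targets with less REPTOR may remain as a hypothesis, found and tested on the same data, while the depth of the knockdown, off-target effects of the dsRNA and a change of total RNA, which scaling removes, were not tested.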

How the results depend on the processing

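Scan day as a fixed block was chosen after seeing the data; the other settings were chosen beforehand. Of 1176 values of 65 named results, 918 kept their direction and their side of the threshold, 217 kept the direction but lost the call, 33 gained a call and 8 reversed. The kept share of the decrease stayed within its spread under every setting run in REPTOR knockdown (main value 76.9%), and moved in REPTOR-BP knockdown with median scaling alone (77.2% against 68.9%). Where fewer arrays entered the fit, a lower count can follow from that alone. The count also depended on which array was left out. For rapamycin in control cells it was 828 without control EtOH replicate 2 and 1152 without control EtOH replicate 1. The cause of that dependence and of the other changes was not tested. The planned check of the knockdown of REPTOR and REPTOR-BP and slide as a fixed block for REPTOR-BP knockdown without rapamycin could not be run. Fitting only the arrays compared was run for counts, and the minimum of 1.5-fold for counts and shares. Signal close to background limits genes such as Polr1B, lncRNA:CR42746, NimC3, Ugt303A1 and CG18233.

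In the following, counts are given in the order rapamycin in control cells, in REPTOR knockdown and in REPTOR-BP knockdown, REPTOR and REPTOR-BP knockdown without rapamycin, and the differences of response of REPTOR and of REPTOR-BP knockdown from control cells, where main counts were 1381, 393, 29, 17, 708, 22 and 1. Slide as a fixed block gave 4233, 1480, 911, 38, no value, 111 and 16. Slide as a random block gave 3980, 1621, 946, 42, 112, 159 and 106. The replicate block gave 2450, 1083, 257, 31, 1843, 63 and 4. Scan day as a block gave 2602, 606, 171, 17, 174, 57 and 2. Median scaling gave 551, 51, 4, 13, 826, 0 and 0. Without a filter on dim probes they were 901, 175, 7, 11, 513, 3 and 1, the last now a larger response. Fitting only the arrays compared gave 94, 0, 0, 0, 3, 10 and 0. Normexp background correction gave 1187, 308, 17, 11, 134, 15 and 2. Quantile normalization gave 1413, 373, 26, 11, 887, 14 and 0. Only probes well above background on all arrays gave 1504, 487, 70, 15, 462, 25 and 1. An intensity trend gave 1526, 496, 79, 14, 690, 45 and 0. The mean of a target's probes gave 1304, 360, 23, 12, 557, 10 and 2, and the deposited values gave 1392, 366, 28, 15, 834, 23 and 0. A minimum of 1.5-fold left 574, 156, 26, 16, 532, 20 and 1. The difference between the knockdowns had 0 limma calls throughout, with 175 at an unadjusted p under 0.05 in the fit as reported, except for 1 without the filter.

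Leaving out each array in turn gave 828 to 1152, 139 to 253, 0 to 8, 9 to 12, 192 to 540, 1 to 10 and 0 to 2 calls, and 0 to 2 for the difference between the knockdowns. Where this left a group with 1 array, that array was assumed to vary like the other groups. The share of higher calls among rapamycin targets in control cells, 51.0%, was 40.7% with median scaling and 39.6% with normexp. In REPTOR knockdown it fell from 34.1% to 15.7% and 22.7%, and in REPTOR-BP knockdown from 24.1% to 0 with both. For REPTOR knockdown without rapamycin it went from 52.9% to 23.1% with median scaling, and for REPTOR-BP knockdown from 22.2% to 52.1% with median scaling, 38.8% with quantile normalization, 38.1% with normexp and 43.2% with the deposited table. The median log2 change of all targets moved from 0.04 to -0.078 for rapamycin in control cells with normexp, and from -0.017 to 0.091 for REPTOR-BP knockdown without rapamycin with median scaling, so changes under these settings are relative to such a shift.

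The share of the increase kept in REPTOR knockdown, 37%, was 30.4% with normexp, 26.0% with median scaling, 33.5% with the deposited table, 30.2% without the filter, 44.6% when targets were selected and measured on the same control arrays and 32.7% at 1.5-fold. In REPTOR-BP knockdown, 42.2% became 39.1%, 28.2%, 40.0%, 38.2%, 45.4% and 39.6%, and leaving out a pair gave 35.0% to 49.2%. The camera call for the mitochondrial ribosomal proteins under rapamycin had an adjusted p of 0.072 with an estimated correlation in each kind of cells. For its difference between REPTOR-BP knockdown and control, 0.075 became 0.048 with quantile normalization, over a range of 0.048 to 0.51. Restricted to probes well above background on all arrays, the correlations of responses rose to 0.604, 0.688 and 0.557.

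Reversed values were log2 changes of 0.03 for CG13545, 0.19 for CG18233 and 0.18 for Ugt303A1 in REPTOR-BP knockdown with normexp. For rapamycin in control cells they were 0.11 for CrebA without control EtOH replicate 3, and -0.04 for RpS18, -0.04 for RpL23 and -0.52 for RpS29 without control rapamycin replicate 1. RpL23 was also at -0.01 with the deposited table. Over all left-out arrays CrebA ran from -0.33 to 0.11, RpS18 from -0.04 to 0.27, RpL23 from -0.04 to 0.29 and RpS29 from -0.52 to 0.91.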

Other observations

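The tests of this part were set out before their results were seen, except for the simulation with the spread within slides and the test with separate control pairs, which were added afterwards.

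Before rapamycin, the targets that rapamycin raises may already have been slightly lower in REPTOR knockdown. Against the held-out control array, the median log2 difference of these targets in ethanol was -0.181, -0.091 and -0.125, below -0.1 in 2 of 3 hold-outs. The rule set beforehand asked for 3 of 3 and counted any median above -0.1 against a lower level. By that rule the value of -0.091 counts against it. Because that value lies close to the limit, the question is left undecided here, which departs from the rule. The targets that rapamycin lowers had 0.03, -0.15 and 0.017 in the same hold-outs. Ypel was at -0.26 ± 0.09 (SE), bchs at 0.93 against 1.13 in control cells on the log2 scale relative to the 75th percentile, and mio at 0.42 against 0.41.

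The 2 knockdowns may in part shift the response of the same targets. Across targets the covariance of the 2 differences from control cells was 0.0434. Simulated groups without a difference but with the same shared control arrays gave a mean of 0.0763, which includes slide differences that cancel within pairs, and simulations with the spread within slides gave 0.0342 and at most 0.0402. With a separate control pair for each difference, so that no control array enters both, the covariance was 0.0201 ± 0.00795 (SD) and above 0 in 6 of 6 choices of pairs, so shared control arrays are argued against as the whole cause. What lies behind the remaining part was not tested.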
